A study of Mus musculus with 6 samples.

How the data were processed

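The 6 samples are RNA-seq libraries of cultured mouse glioma cells, 3 of GL261 and 3 of mNS neurospheres. Total RNA was depleted of ribosomal RNA and made into stranded libraries, which were read from a single end, per the labels' protocols. The submitters' processing notes name TopHat2 (version 2), HTSeq 0.5.3p9, edgeR 3.4.2 and the mouse build mm10, with no roles or order given. The series text describes TMM scaling factors, tagwise dispersions, an exact test and Benjamini-Hochberg adjustment in edgeR. The deposited table holds 1 normalised signal per gene and library, in CPM (read counts scaled to a common library size) with TMM factors, per the labels and the file's name. The columns add up to between 968335 and 1037864, which differs from the fixed total of plain CPM, so the unit is described as a signal.

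The table lists 12151 genes by symbol. The limit below which genes were left out is not given in the sources used here. The lowest number of reads over all 6 libraries was 46, and 12123 genes had at least 1 CPM in 3 or more libraries. Low values in each column were whole multiples of a single step, the worth of 1 read. Divided by that step, 100% of the values came out whole within 0.001 reads. These recovered reads gave the depth: 13825692, 13885302 and 14225175 reads in listed genes for GL261 replicates 1 to 3 (passages 17, 33 and 34), and 12826599, 12534422 and 13689479 for mNS replicates 1 to 3 (passages 72, 77 and 85). Reads outside the listed genes are not analysed here.

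The main test was limma 3.58.1 in R 4.3.3: lmFit and eBayes with trend, two-sided, on log2(CPM + 1), with Benjamini-Hochberg adjustment over the 12006 genes with a mean of at least 1 CPM; 145 genes lay below. A gene was called at an adjusted p under 0.05. Fold changes given as log2 differences are on the log2(CPM + 1) scale, which understates the change of genes with low values; folds given as N-fold are ratios of group means of CPM. Group values are means ± SD over 3 libraries. Where a group had no read, the fold is a lower bound against 3 reads per library (0.222 CPM on average in GL261 and 0.224 CPM in mNS). Where a group had 1 to 3 reads, the ratio has an exact 95% binomial (Clopper-Pearson) interval. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

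Before the data were examined, 37 gene lists were written for the tissue, the media and the cell types a glioma culture could hold. The rule for named genes was also fixed then. It takes the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 10 CPM, leaving out numbered gene models, clone names ending in Rik, small RNAs, ribosomal protein genes and mitochondrial genes. It adds up to 4 called members of each list, those with the largest differences (up to 2 with the highest mean where none was called), and 15 fixed markers, and named 156 genes. Of the 715 symbols fixed, 528 list genes were in the table, 4 of them under an older symbol. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01, two-sided, adjusted over 32 lists), beside camera with an estimated correlation and fry. Fry asks whether the genes of a list move, on balance, one way, or in its mixed form whether they change in either direction, and compares the list with no other genes.

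Count tests were run on the recovered reads as alternatives: edgeR 4.0.16 by quasi-likelihood called 7654 genes, 7624 of them with the same direction in limma, its exact test called 7499 and DESeq2 1.42.0 called 7353. All 4 tests called 7164 genes. Other alternatives were pseudocounts of 0.5 and 0.1, other filters, 3 rescalings, limma without trend or with array weights, an adjusted p under 0.01, a test against a 2-fold change, and leaving out each library in turn, for which ratios of group means that moved by over 1.5 times are given beside the gene. Simulated data were drawn from the means and depths of this comparison, with 11982 genes tested. In them limma called 48.0% of genes changed 1.5-fold, 84.0% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. Of its calls 8.79% were unchanged genes, as were 8.29% in edgeR's quasi-likelihood test, 16.7% in its exact test and 14.2% in DESeq2. The simulation changed a far smaller share of genes than the 64.3% called in the data, so these rates need not hold there.

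Positions come from GENCODE M21 (GRCm38, the assembly of mm10), to which 12040 of the 12151 symbols were matched, 608 by a synonym. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, position statistics and plots. The values by passage within GL261 carry no test. The protocol also mentions human glioma cultures, which are not analysed here.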

Results

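RNA was sequenced from mouse glioma cells kept in culture in either of 2 forms. GL261, a glioma line of mouse origin, grew in medium with serum, and its libraries are labelled as differentiated glioma cells. The cells named mNS grew as floating neurospheres in serum-free medium with EGF, basic FGF and heparin, and their libraries are labelled as glioma stem-like cells. Each group had 3 libraries, which differed in passage: 17, 33 and 34 for GL261 (the passage field of the third says 33 while its title says 34), and 72, 77 and 85 for mNS. The deposited table lists 12151 genes, and between 12534422 and 14225175 reads per library fell in them. Values are in CPM, read counts scaled to the size of the library, and 1 read was worth between 0.0708 and 0.0773 CPM. The labels do not say that the libraries of a group came from separate cultures apart from their passage, so the p-values measure the spread between these libraries.

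The libraries separated by cell form. Across 12006 genes, Pearson's r of log2(CPM + 1) lay between 0.987 and 0.997 for pairs within a group and between 0.845 and 0.856 for pairs from different groups; these are correlations across genes, which are not independent replicates. Within GL261, passages 33 and 34 were the closest pair (r = 0.997) and passage 17 lay further from both (0.990 and 0.989). Within mNS, passages 77 and 85 were the closest pair (r = 0.996). No pair agreed within counting noise: the chi-square of read counts per degree of freedom was at least 3.14. All 6 libraries were kept as separate samples. The measure covers counting error only and cannot show that the libraries came from separate cultures.

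The comparison of mNS with GL261 asks how stem-like glioma cells differ from serum-grown glioma cells in the genes they express. Cntn1, an adhesion molecule of neurons and glia (chromosome 15, 92051165 to 92341967 in GRCm38), rose from 1.11 ± 0.149 CPM in GL261 to 858 ± 78.2 CPM in mNS (SD, n = 3 each), a log2 difference of 8.67 ± 0.09 (SE; limma adjusted p = 3.45e-10). In the other direction Fn1, which encodes the matrix protein fibronectin (chromosome 1, 71585520 to 71653200), fell from 1029.7 ± 68.7 CPM in GL261 to 1.81 ± 0.214 CPM in mNS (log2 difference -8.52 ± 0.09, adjusted p = 3.45e-10). Of the 12006 genes tested, 7714 (64.3%) were called at an adjusted p under 0.05 in limma, 3865 higher and 3849 lower in mNS. A change of at least 2-fold, here an absolute difference of at least 1 in log2(CPM + 1), was called for 2370 genes, 1353 higher and 1017 lower. An absolute log2 difference of at least 3 was found for 380 of the called genes, 190 in each direction. The values of the groups did not overlap for 8397 genes (69.9%), where chance alone gives 10%. Cell line, medium and passage range changed together between the groups, so that the comparison cannot assign a difference to any one of them. Tested against a 2-fold change as the null, 1414 genes were called. The balance of directions in the main test depended on the scaling. With the columns rescaled to a common sum, 4460 genes were called higher and 3197 lower in mNS. With each library centred on its median gene the counts were 3711 and 4040, and under quantile normalisation 3836 and 3874.

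The other 11 of the 12 genes with the largest rises had varied known roles. Tnc, the matrix glycoprotein tenascin C, stood at 0.270 ± 0.169 CPM in GL261 and 137 ± 22.7 CPM in mNS (log2 difference 6.76). Ptprz1, a receptor phosphatase of glial progenitors, rose 97.4-fold, from 5.02 ± 1.19 to 489 ± 7.02 CPM, and Sema3a, a secreted axon guidance factor, rose from 1.14 ± 0.963 to 286 ± 19.2 CPM. Fam19a4, which encodes a small secreted protein, had 2 reads over the 3 GL261 libraries and 9439 over the 3 mNS libraries, a ratio of 4758 with a 95% counting interval of 1317 to 39297. Prom2, a relative of the stem cell marker prominin, had no read in any GL261 library and 62.9 ± 5.84 CPM in mNS, which is at least 284-fold higher when GL261 is set to 3 reads per library. Mga, a transcription factor that pairs with MAX, rose from 0.198 ± 0.156 to 123 ± 1.66 CPM. The neuropeptide gene Nts (log2 difference 6.31), the channel-binding protein gene Kcnip3 (6.12), the protocadherin Pcdh15 (6.08) and the transcription factor Klf12 (5.98) complete the list with the imprinted noncoding RNA H19, whose mNS values were 586, 301 and 133 CPM at passages 72, 77 and 85, against a mean of 1.25 CPM in GL261. When GL261 replicate 1 was left out, the fold between group means moved from 251 to 485 for Sema3a, from 620 to 1109 for Mga and from 215 to 352 for Klf12; without mNS replicate 1 that of H19 moved from 272 to 173.

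The other 11 of the 12 genes with the largest falls also had varied known roles. Fgfr3, a receptor for fibroblast growth factors, fell from 872 ± 160 to 1.70 ± 1.21 CPM (log2 difference -8.41), and Nrp1, a coreceptor for semaphorins and VEGF, fell from 310 ± 32.7 to 0.595 ± 0.347 CPM (-7.62). Sorbs2, an adaptor of the actin cytoskeleton, fell by 7.64 on the log2 scale, the matrix collagen gene Col12a1 by 7.07 and the secreted lysophospholipase gene Enpp2 (autotaxin) by 7.01. The protease gene Klk8 had 7131 reads in GL261 and 2 in mNS, a ratio of 3536 with a 95% counting interval of 979 to 29206. The surface antigen gene Ly6a varied within GL261 (310 ± 177 CPM) and stood at 0.823 ± 0.394 CPM in mNS. The X-linked Pet2 (-7.25), Vgll3, a cofactor of TEAD transcription factors (-6.92), the phospholipase gene Plce1 (-6.77) and the linker histone gene Hist1h1b (-7.04) were the other members of the 12 largest falls. The size of some falls rested on single mNS libraries: the fold between group means moved from 514 to 873 for Fgfr3 and from 534 to 1191 for Plce1 without replicate 1, from 751 to 1459 for Sorbs2 without replicate 2, and from 169 to 395 for Hist1h1b without replicate 3.

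**Figure D1:**
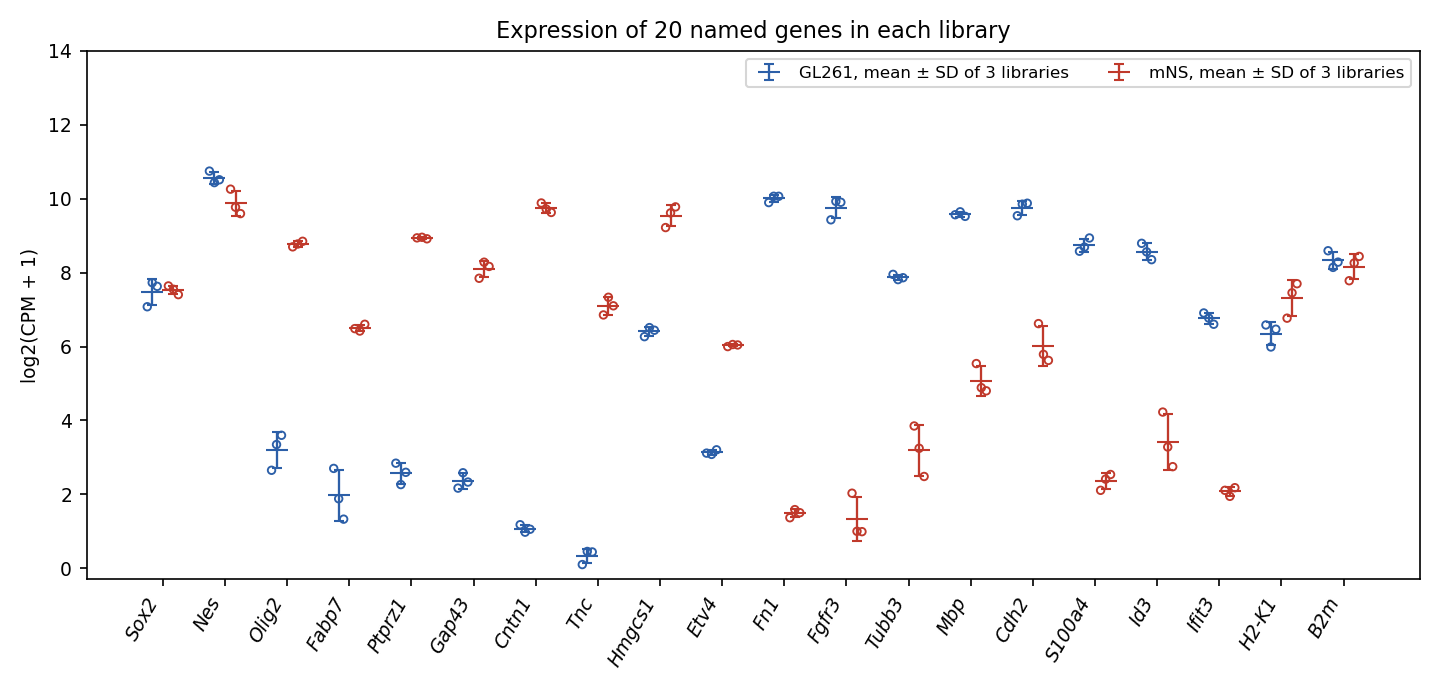
Expression of 20 named genes in each of the 6 libraries, as log2(CPM + 1) on the vertical axis. Open points are single libraries and horizontal bars with whiskers are the mean ± SD of the 3 GL261 (blue) or 3 mNS (red) libraries; Cntn1 lies 8.67 higher in mNS, Fn1 lies 8.52 lower, and the points of Sox2 and B2m overlap between the groups.

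Lists of genes fixed before the data were examined were counted in the same fit and tested with camera, which compares a list with all other tested genes. Of 524 list genes tested, 403 were called. Camera with a preset correlation of 0.01 called 8 of 32 lists, 2 higher and 6 lower in mNS. With a correlation estimated from the data it called 0 lists, and 4 had an unadjusted p under 0.05, while fry called 23 lists in its directional form and 32 in its mixed form. Regrouping the same 6 libraries in other ways gave up to 8 lists called by camera with the preset correlation.

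Markers of neural lineages went both ways, and the values of the stem cell regulator gene Sox2 overlapped between the groups: 181 ± 41.0 CPM in GL261 and 184 ± 15.1 CPM in mNS, a log2 difference of 0.05 ± 0.16 (limma adjusted p = 0.778), which was -0.15 without GL261 replicate 1, -0.00074 without mNS replicate 1 and -0.08 with array weights, without a call. Of 15 neural stem and progenitor genes, 6 rose in mNS and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.773). The risers included the transcription factor genes Olig2, from 8.54 ± 2.97 to 437 ± 22.8 CPM (51.1-fold), and Olig1 (23-fold), and the fatty acid binding protein gene Fabp7 (27.7-fold, and 42.7-fold without GL261 replicate 1), all typical of glial progenitors. The Notch target Hes1 fell 20.7-fold, Notch1 fell from 197 ± 18.8 to 67.3 ± 2.90 CPM, and the intermediate filament gene Nes, a common marker of neural stem cells, fell from 1518 ± 175 to 955 ± 236 CPM (log2 difference -0.69, adjusted p = 0.00472). Prom1 and Egfr were not listed in the table.

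Of 14 oligodendrocyte lineage genes, 10 rose and 3 fell, with the same counts when adjusted over the list alone. The surface receptor gene Pdgfra, a marker of oligodendrocyte progenitors, rose 2.42-fold, Sox8 rose 34.1-fold, and Mog, which encodes a myelin surface protein, went from 3 to 647 reads, a ratio of 217 with a 95% counting interval of 74.1 to 1057 (443 without GL261 replicate 1). The myelin gene Mbp went the other way, from 763 ± 33.3 to 33.7 ± 10.3 CPM. The other genes of the list that fell were Cspg4 (log2 difference -1.38) and Sox10 (-0.91), both named after their values were seen. The list test missed the threshold (camera adjusted p = 0.0933) and passed it without GL261 replicate 1, the passage 17 library (0.0370); over all libraries the adjusted p was 0.642 with an estimated correlation. Of 13 astrocyte genes 4 rose and 5 fell (4 and 6 when adjusted over the list alone; camera adjusted p = 0.699). Aldoc, a glycolytic enzyme of astrocytes, rose 6.73-fold; S100b fell 4.31-fold, the filament gene Gfap fell from 3.45 ± 1.81 to 0.101 ± 0.115 CPM (34.1-fold, and 89.3-fold without mNS replicate 1), and Aldh1l1 had no read in any mNS library, which is at least 36.6-fold lower than its GL261 level of 8.19 ± 3.90 CPM. The other astrocyte genes that rose were Slc1a3 (log2 difference 1.74), Sparcl1 (1.67) and Clu (0.36), and Fgfr3 and Glul (-0.86) also fell. Of these, all but Fgfr3 were named after their values were seen. All 5 neuronal genes tested changed, 3 up and 2 down (camera adjusted p = 0.677), where 64.3% of all tested genes were called. Gap43, a growth cone protein, rose 65.8-fold and the synaptic vesicle gene Syt1 8.33-fold. Tubb3, the tubulin used as a neuronal marker, fell 26.4-fold and Ncam1 20.7-fold. The other riser, Map2, was named after its value was seen. Other neuronal markers fixed beforehand, such as Dcx, Rbfox3, Snap25 and Syp, were not listed in the table.

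**Figure D2:**
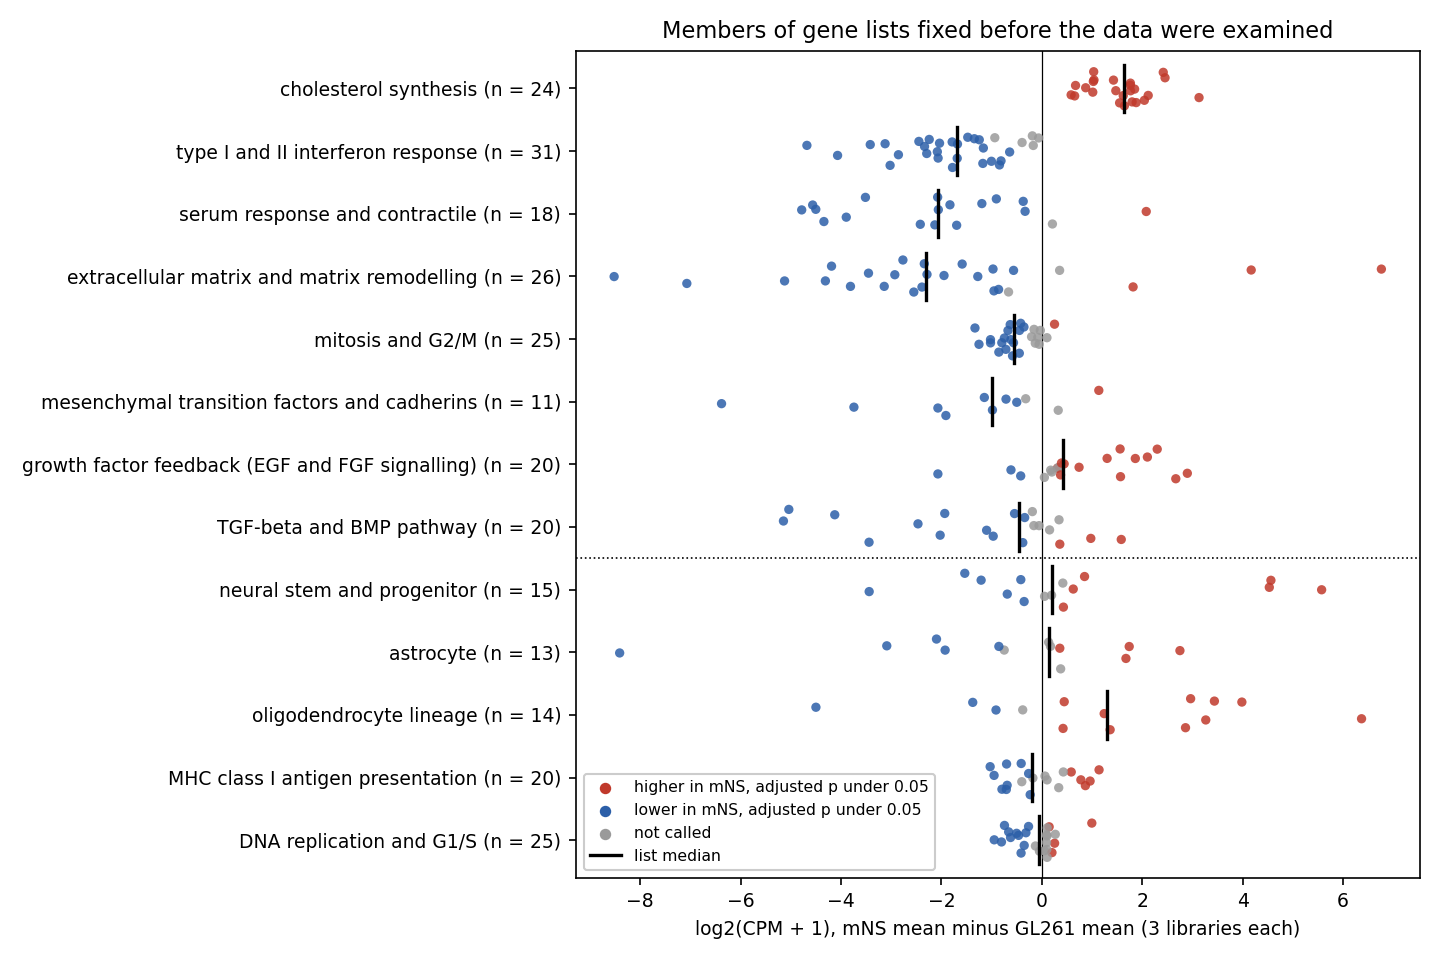
Log2 differences between mNS and GL261 on the log2(CPM + 1) scale (horizontal axis) for the members of 13 fixed gene lists (vertical axis); each point is a gene, coloured by its call, and black bars are list medians. The 8 lists above the dotted line were called by camera with a preset correlation; all 24 cholesterol synthesis genes lie above 0 and all 31 interferon response genes lie below 0.

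Most of the matrix, contractile and mesenchymal genes tested were lower in the neurospheres. Of 26 matrix genes 21 fell and 3 rose, with the same counts when adjusted over the list alone (camera adjusted p = 1.36e-05; adjusted p = 0.400 with an estimated correlation). Beside Fn1 and Col12a1, the collagen crosslinking enzyme gene Loxl2 fell from 38.3 ± 3.31 to 0.125 ± 0.0474 CPM; the risers were Tnc, Thbs2 (log2 difference 4.17) and Vcan (1.82), of which the latter pair were named after their values were seen. Among 18 genes of the serum response and the contractile apparatus 16 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 1.68e-06; adjusted p = 0.306 with an estimated correlation). The matricellular genes Ctgf and Cyr61 fell 160-fold and 24.3-fold, the smooth muscle actin gene Acta2 91.8-fold (161-fold without mNS replicate 3) and the myosin light chain gene Myl9 57.2-fold; Ctgf had 8 and Acta2 11 reads over the mNS libraries, so that their folds are imprecise. The riser was another actin gene, Actg2 (log2 difference 2.08), picked out after its value was seen. Of 11 mesenchymal transition factors and cadherins 8 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00675; adjusted p = 0.306 with an estimated correlation). The calcium-binding protein gene S100a4 fell 103-fold, Cdh2, the neural cadherin, 13-fold, the AP-1 member Fosl1 6.95-fold and Prrx1 3.83-fold. The riser was the transition factor gene Twist1 (log2 difference 1.13, from 5.19 ± 0.891 to 12.5 ± 1.04 CPM), named after its value was seen. Zeb1 and Cebpb were not called. The abundant filament gene Vim fell from 7257 ± 617 to 3659 ± 117 CPM and the hyaluronan receptor gene Cd44 from 394 ± 12.6 to 240 ± 19.7 CPM.

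Genes of TGF-beta and BMP signalling were also lower in mNS. Of 20 genes 12 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.623 with an estimated correlation). The BMP target genes Id3 and Id1 fell 35.5-fold and 20.1-fold, the inhibitory Smad7 fell 20.8-fold, and the ligand gene Tgfb2 fell from 36.0 ± 5.22 to 0.124 ± 0.158 CPM, which is 290-fold, or 1017-fold without mNS replicate 1. Integrin genes split by member: 5 of 17 rose and 9 fell (camera adjusted p = 0.276), the same when adjusted over the list alone. Itga1 fell 35.2-fold, Itga2 23.6-fold and Itgb3 15.6-fold. Itga4, whose product binds fibronectin and VCAM1, rose from 102 ± 27.4 to 2333 ± 261 CPM.

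Feedback genes of the EGF and FGF pathways were higher in mNS, the cells whose medium held those factors. Whether the medium caused the rise was not tested, and Egfr, the EGF receptor gene, was not listed in the table. Of 20 genes 13 rose and 3 fell (14 and 3 when adjusted over the list alone; camera adjusted p = 0.00675; adjusted p = 0.306 with an estimated correlation). The ETS factor genes Etv4 and Etv1 rose 8.27-fold and 5.68-fold, and the signalling inhibitor genes Spry4 and Spry2 rose 6.74-fold and 4.25-fold. The genes that fell were Fosl1, Fos (log2 difference -0.62) and Spred1 (-0.42), the last named after its value was seen. All 15 growth factor receptor genes tested were called, 8 higher and 7 lower, the same when adjusted over the list alone (camera adjusted p = 0.860). Besides Fgfr3, Epha2 fell 75.9-fold and Axl 5.35-fold, while Kit, the receptor for stem cell factor, rose 5.36-fold.

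Notch, Wnt and Hedgehog genes moved without a common direction. Of 17 Notch pathway genes 4 rose and 6 fell (camera adjusted p = 0.532). Nrarp, a Notch target that feeds back on the pathway, fell 37.3-fold (86.3-fold without mNS replicate 1) with Hes1, whereas the glycosyltransferase gene Mfng rose 34.4-fold (55.7-fold without GL261 replicate 1). The ligand gene Dll3 rose from 2.61 ± 1.33 to 19.5 ± 17.2 CPM, 7.47-fold with all libraries and 3.70-fold without mNS replicate 1. Of 14 Wnt pathway genes 5 rose and 7 fell (camera adjusted p = 0.699). The ligand gene Wnt7b rose 134-fold (204-fold without GL261 replicate 3) and Dkk3 21.4-fold (42.1-fold without GL261 replicate 1), the receptor gene Fzd1 fell 6.38-fold, and the secreted inhibitor gene Wif1 had 237 reads in GL261 and 2 in mNS, a ratio of 118 with a 95% counting interval of 32.2 to 976. Of 6 Hedgehog pathway genes 3 rose and 1 fell (camera adjusted p = 0.699): the coreceptor genes Cdon and Boc rose 4.04-fold and 2.51-fold and Smo 1.31-fold, and Gli3 fell 1.83-fold. For these 3 lists the counts were the same when adjusted over the list alone.

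Interferon response genes were lower in the neurospheres, 26 of 31 falling and the other 5 lying below 0 without a call, also when adjusted over the list alone (camera adjusted p = 1.50e-07; adjusted p = 0.642 with an estimated correlation). The antiviral genes Ifit3 and Ifit1 fell from 108 ± 11.5 to 3.24 ± 0.347 CPM and from 153 ± 10.6 to 8.19 ± 1.23 CPM. The chemokine gene Cxcl10 fell 10.9-fold and Isg15, a ubiquitin-like modifier, fell 9.65-fold. Relative to each gene's mean over the 6 libraries, the list median was 1.11, 0.70 and 0.82 on the log2 scale in GL261 at passages 17, 33 and 34, and -1.22, -0.96 and -0.34 in mNS at passages 72, 77 and 85. Antigen presentation genes went both ways. Of 20 MHC class I pathway genes 5 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.521). The class I heavy chain gene H2-K1 rose from 81.6 ± 17.0 to 163 ± 50.4 CPM (limma adjusted p = 0.00665) and the peptide transporter gene Tap2 rose 2.24-fold, while the immunoproteasome gene Psmb10 fell 1.95-fold and Tapbpl 2.24-fold. B2m, the class I light chain, stood at 326 ± 53.3 CPM in GL261 and 290 ± 64.9 CPM in mNS (log2 difference -0.18 ± 0.17, adjusted p = 0.381), and the difference was 0.01 without mNS replicate 1 and 0.02 with array weights, without a call. The 2 class II loading genes measured, H2-DMb1 and H2-DMa, rose 1.76-fold and 1.52-fold, also when adjusted over the list alone. The class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 were not listed in the table. The call of H2-DMa ended when GL261 replicate 2 or 3 or mNS replicate 1 or 3 was left out. Its limma adjusted p was then between 0.0630 and 0.0891. The call also ended under quantile normalisation (0.132) and in DESeq2 (0.0547).

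Among 25 cytokine, chemokine and immune ligand genes 11 rose and 6 fell, the same when adjusted over the list alone (camera adjusted p = 0.531). The alarmin gene Il33 rose 8.40-fold from 13.9 ± 5.53 CPM, the prostaglandin synthase gene Ptges 10.9-fold and the ectonucleotidase gene Nt5e 9.30-fold; the galectin gene Lgals3 fell 5.60-fold. Cd274, which encodes the checkpoint ligand PD-L1, stood at 3.23 ± 0.271 CPM in GL261 and 2.24 ± 0.611 CPM in mNS (log2 difference -0.40 ± 0.17, adjusted p = 0.0677); without mNS replicate 3, the passage 85 library, the difference was -0.54 and was called (adjusted p = 0.0234). Cd274 was also called under quantile normalisation (-0.62, adjusted p = 0.0104), in limma without trend (0.0408) and with array weights (0.000996). Of 15 genes used as glioma antigens 5 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.808). Tnc, Ptprz1 and Fabp7 were among the risers, and Epha2 was among those that fell.

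Mitotic genes were lower in mNS by small factors. Of 25 genes of mitosis and G2/M 17 fell and 1 rose (18 and 1 when adjusted over the list alone; camera adjusted p = 7.17e-05; adjusted p = 0.642 with an estimated correlation). Prc1 and Kif20a, which act in cytokinesis, fell 2.53-fold and 2.41-fold, and the mitotic transcription factor gene Foxm1 fell 2.05-fold. The proliferation marker Mki67 fell from 1558 ± 34.6 to 860 ± 16.8 CPM. The riser was Cenpe (log2 difference 0.25), named after its value was seen. Of 25 genes of DNA replication 4 rose and 11 fell, the same when adjusted over the list alone (camera adjusted p = 0.519). Cdt1, a licensing factor, fell 1.96-fold and the ribonucleotide reductase gene Rrm2 1.76-fold, while Uhrf1, which couples replication to DNA methylation, rose 2.0-fold. Of 21 cell cycle inhibitor and p53 target genes 7 rose and 5 fell, the same when adjusted over the list alone (camera adjusted p = 0.699). Trp53inp1 and Bbc3 rose 3.75-fold and 3.23-fold, and Phlda3 and the CDK inhibitor gene Cdkn2c fell 3.26-fold and 2.88-fold.

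Every gene of cholesterol synthesis and its control that was tested was higher in mNS: 24 of 24, also when adjusted over the list alone (camera adjusted p = 1.41e-09; adjusted p = 0.623 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, rose from 84.1 ± 7.30 to 751 ± 144 CPM, Sqle, the squalene epoxidase gene, rose 5.50-fold, the sterol reductase gene Tm7sf2 6.50-fold and the sterol sensor gene Insig1 4.40-fold. Of 15 fatty acid synthesis genes 8 rose and 2 fell (camera adjusted p = 0.0801), a list that was called without mNS replicate 1 (0.0163) and under quantile normalisation (0.0255), but not with an estimated correlation over all libraries (adjusted p = 0.810). The acetyl-CoA synthetase gene Acss2 rose 8.01-fold, Acsl3 3.12-fold and Elovl6 2.63-fold, and the malic enzyme gene Me1 fell 3.29-fold. Of 22 glycolysis genes 11 rose and 8 fell (camera adjusted p = 0.699): the glucose transporter gene Slc2a1 rose 2.38-fold while Slc2a3 fell 2.62-fold, and Ldhb rose 2.61-fold. Of 17 hypoxia target genes 11 rose and 2 fell (camera adjusted p = 0.0933), Egln3 rising 2.30-fold and Ero1l 2.17-fold and P4ha2, a collagen hydroxylase gene, falling 2.48-fold. Of 31 genes of oxidative phosphorylation 8 rose and 12 fell (camera adjusted p = 0.606), among them the complex I subunit gene Ndufs1, which fell from 292 ± 1.20 to 168 ± 1.40 CPM, and the succinate dehydrogenase gene Sdhb, which fell 1.62-fold. Cycs and the X-linked Ndufa1 rose 1.59-fold and 1.84-fold. Adjusting over the list alone gave the same counts except in glycolysis, where 9 fell.

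Imprinted and oncofetal genes gave 3 rises and 5 falls among 12 (camera adjusted p = 0.587). H19 and Plagl1 rose, the latter 9.96-fold, while the growth factor gene Igf2 fell 41.2-fold and Peg3 6.63-fold. Of 5 pluripotency factor genes Tfcp2l1 rose 5.82-fold and Myc 1.69-fold with a further riser, Dppa4 (log2 difference 0.38, named after its value was seen), while Klf4 and Klf2 fell 8.29-fold and 3.28-fold (camera adjusted p = 0.777). Of 14 genes of a list on drug efflux, aldehyde dehydrogenases and DNA repair linked to resistance, which also held detoxification and surface marker genes, 6 rose and 4 fell (camera adjusted p = 0.699); its DNA repair gene Mgmt was not listed in the table. In this list the efflux pump gene Abcc4 rose 3.06-fold and Hmox1 3.04-fold, and the surface marker gene Cd24a fell 32.4-fold. The counts of these 3 lists were the same when adjusted over the list alone. The list median, the list mean and the test differed in sign for astrocyte genes, growth factor receptors, the Wnt pathway, glioma antigens, pluripotency factors, drug efflux, immediate early genes and the unfolded protein response.

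Markers of other cell types were counted in the same way. Of the microglia and macrophage markers 3 were tested: Cd68 rose from 2.95 ± 0.156 to 8.09 ± 1.32 CPM, Tmem119 rose from 0.640 ± 0.158 to 1.64 ± 0.0202 CPM and Lyz2 fell from 5.30 ± 1.62 to 1.31 ± 0.614 CPM. Of 3 endothelial markers Eng fell, from 1.82 ± 0.422 to 0.348 ± 0.119 CPM. Of 5 fibroblast and pericyte markers 2 rose and 2 fell (camera adjusted p = 0.755): the collagen gene Col1a1 fell 20.5-fold from 127 ± 9.75 CPM and Pdgfrb 19.5-fold from 2.41 ± 0.748 CPM, while Des rose 6.25-fold to 8.63 ± 2.51 CPM, beside Pdgfra. These counts were the same when adjusted over each list alone. Other fixed markers of microglia and macrophages, such as Ptprc, Aif1, Itgam and Cx3cr1, were not listed in the table. Neither were the endothelial markers Pecam1, Cdh5 and Kdr, nor the red blood cell markers.

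Genes that respond to handling and stress went both ways. Of 12 immediate early and heat shock genes 2 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.695): Atf3 rose 2.79-fold and Ier2 1.46-fold, Fos fell 1.54-fold, and Jun fell 1.30-fold, a call that ended when replicate 2 or 3 of either group was left out (adjusted p between 0.0578 and 0.0782) or the columns were rescaled to a common sum (0.0612). Of 15 unfolded protein response genes 2 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.318): Slc7a11, a cystine transporter gene, rose 8.44-fold (17.5-fold without GL261 replicate 1) and Trib3 3.21-fold, and the chaperone genes Dnajb9 and Hsp90b1 fell 1.80-fold and 1.42-fold. Nuclear noncoding RNAs went both ways, also when adjusted over the list alone: Malat1 rose 1.86-fold, Neat1 2.80-fold and Airn 1.91-fold, and Kcnq1ot1 fell 2.03-fold. The ribosomal RNA precursor Rn45s took between 1.09% and 1.24% of the table in GL261 and between 0.554% and 0.697% in mNS.

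Hist1h1b, one of the 12 largest falls, lies on chromosome 13 (21779883 to 21780625) within a group of histone genes, and the other histone genes were looked at after its value was seen. Of 53 histone genes tested, the 12 between 21716422 and 21832196 all fell in mNS, with log2 differences between -7.04 and -2.82. These 12 genes mark a segment whose bounds were drawn from the log2 differences themselves. Together they summed to 1406 ± 71.5 CPM in GL261 and 15.8 ± 8.83 CPM in mNS (SD, n = 3 each), with 9.21, 12.4 and 25.8 CPM at passages 72, 77 and 85. The 41 histone genes outside that segment had a median log2 difference of -0.18, and the 28 in the second group on the same chromosome, from 23531050 to 23764406, had a median of -0.17. Hist1h2bl, whose gene ends at 21716143, was at -0.89 (limma adjusted p = 0.0003135), and the flanking zinc finger genes Zkscan8 and Zfp184 were at 0.66 (adjusted p = 0.000130) and 0.13. Histone genes are near-identical copies, so the value of any 1 copy is uncertain where a read could be counted for several.

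**Figure D3:**
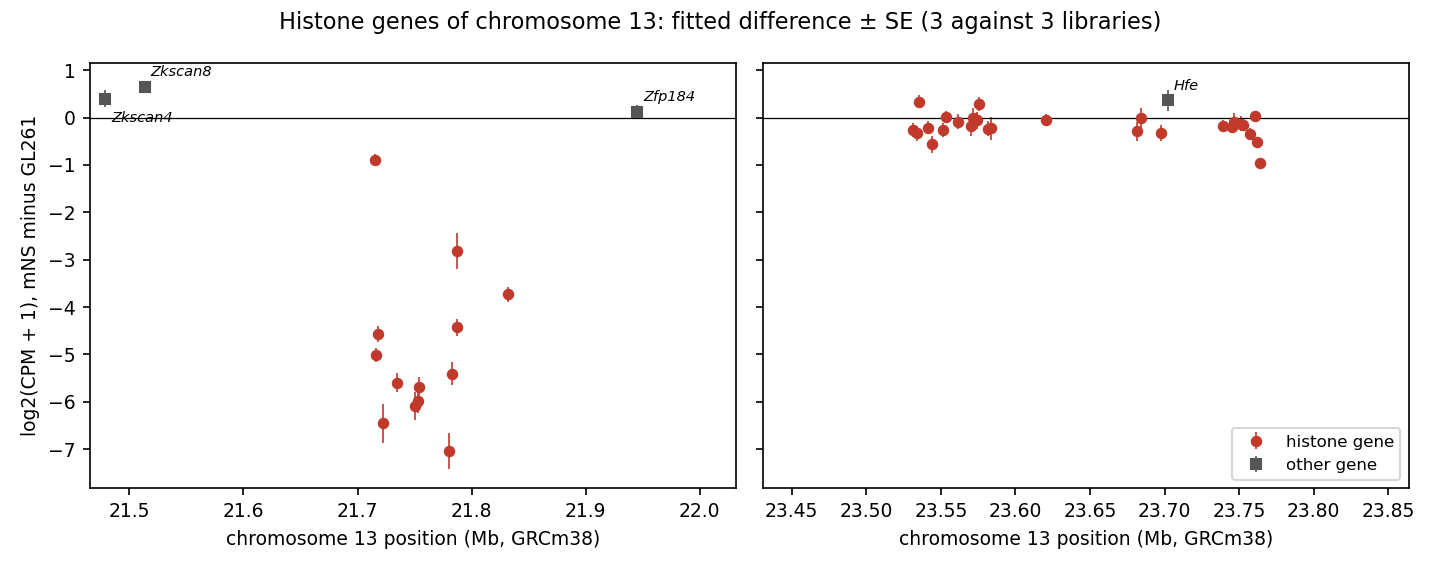
Map of the histone genes of chromosome 13 (GRCm38 position in Mb, horizontal axis) with their fitted log2 difference between mNS and GL261 ± SE (vertical axis; 3 libraries per group). In the left panel 12 neighbouring histone genes lie between -2.82 and -7.04 while Hist1h2bl is at -0.89, Zkscan8 at 0.66 and Zfp184 at 0.13; the second group of 28 histone genes in the right panel has a median of -0.17.

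Within GL261, 1 early library (passage 17) can be set beside 2 later ones, with no test because the early passage has 1 library. Hmcn1, which encodes a large matrix protein, was at 32.9 CPM at passage 17 and at 1.20 and 1.66 CPM at passages 33 and 34. The 4 other genes furthest above both later libraries were Sdpr (56.4 against 8.22 and 11.1 CPM), Cass4 (15.9 against 2.99 and 2.60 CPM), the protease inhibitor gene Serpine2 (22.6 against 4.86 and 3.54 CPM) and Slc7a11 (33.3 against 8.0 and 7.73 CPM). The 5 furthest below were Arl4c (2.83 against 15.7 and 27.2 CPM), the glutathione transferase gene Gstm1 (17.1 against 69.6 and 67.7 CPM), Ncam1 (6.56 against 26.1 and 28.2 CPM), the matrix glycoprotein gene Reln (11 against 38.9 and 45.7 CPM) and Wif1 (1.64 against 7.47 and 8.31 CPM). With a pseudocount of 0.1 in place of 1, 8 of these 10 genes were again chosen.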

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

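All alternatives in this part were fixed before the data were examined. The count of 7714 called genes lay within 1.5 times of its value under every pseudocount, filter, rescaling and count test tried, from 6081 (adjusted p under 0.01) to 9488 (limma with array weights), and no called gene was called in the opposite direction. Leaving out 1 library at a time gave 6603 to 7781 called genes, 2338 to 2446 at least 2-fold, 367 to 408 called list genes and 8 to 9 called lists. Under the pseudocounts, filters, rescalings and count tests, the count at least 2-fold ran from 1810 (mean of at least 5 CPM) to 2666 (edgeR's exact test). Limma's test against a 2-fold change called 1414 genes where 2370 passed a threshold of 2-fold after the test, because it asks for evidence beyond that fold. Camera called 0 lists with an estimated correlation (4 at an unadjusted p under 0.05) where it called 8 with the preset one, and fry called 23 in its directional and 32 in its mixed form. Fry's directional form also turned the direction of glioma antigens (higher, adjusted p = 0.0004108), of pluripotency factors (lower, adjusted p = 0.03579) and, without a call, of the Wnt pathway (higher, adjusted p = 0.105), and the cause was not tested; camera called none of these lists. The 8 called lists were also called with each library left out and under the 3 rescalings, with an adjusted p of at most 0.0156. The highest r between groups moved from 0.856 to 0.8613 with no filter and to 0.8177 without the 1000 most abundant genes, which follows from the genes counted. Of 2788 values of 156 named genes under 18 settings, 2773 stayed on their side of the threshold, 11 lost the call, 4 gained one and 0 calls turned direction; the changes of call concern Jun, H2-DMa and Cd274. Sox2 and B2m, which were not called, changed sign under array weights and with some libraries left out. No paired analysis was possible because the labels give no replicate numbers and the groups share no passage; the numbers 1 to 3 used here only name the libraries. Depth limits genes with few reads in a group: their folds are bounds at 0 reads, have intervals at 1 to 3 reads and are imprecise just above that.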

Other observations

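The tests in this part were chosen after the results they bear on were seen, except the test on GC content and transcript length, which was set before its result was known. Neighbouring imprinted genes at the end of chromosome 7 went in opposite directions. H19 (142575529 to 142578143) rose from 1.25 ± 0.364 CPM in GL261 to 340 ± 229 CPM in mNS, and Igf2 (142650766 to 142666816) fell from 24.3 ± 3.91 to 0.589 ± 0.226 CPM (SD, n = 3 each). Both were called in limma (adjusted p = 2.30e-06 and 1.79e-07), and both groups of values were apart in all 6 libraries. Without mNS replicate 1 the fold of H19 moved from 272 to 173.

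Whole chromosomes differed between the cell forms by small amounts. The median log2 difference of autosomes lay between -0.30 (chromosome 18, 320 genes) and 0.28 (chromosome 16, 391 genes, of which 75.4% were higher in mNS). Passage 17 of GL261 stood apart from the later passages on some of them. Relative to the mean of all 6 libraries, its median was 0.17 on chromosome 4 against 0.04 and 0.03 in passages 33 and 34, -0.20 on chromosome 13 against 0.02 and -0.04, and 0.04 on chromosome 18 against 0.20 and 0.17. No test was run on these values of single libraries.

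The loss of histone RNA from 1 segment of chromosome 13 in mNS was followed up. The segment was bounded by the log2 differences themselves, so its 12 genes, with a median of -5.50, were low by choice. A general loss of histone RNA is argued against by the 41 histone genes outside the segment. Their median log2 difference was -0.1841, with 10th and 90th percentiles of -0.57 and 0.34. The 28 genes of the second chromosome 13 group, set apart by position alone, had a median of -0.17. Reads moved to near-identical copies elsewhere would raise the sum outside the segment. That sum was 7727 ± 703 CPM in GL261 and 6754 ± 1232 CPM in mNS, a difference of -972.5 CPM, so no gain was seen. Its spread between libraries is too wide to exclude a gain of the size lost inside (from 1406 to 15.8 CPM), so this explanation is not decided. Loss or silencing of 1 chromosome segment stays open: it would lower other genes inside the segment too, but 0 listed genes there are no histone genes, so that no value decides. RNA does not show copy number, and the cell line, medium and passage were not tested.

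X-linked genes were mostly higher in mNS: the median log2 difference of 411 genes was 0.5296 (95% bootstrap interval 0.43 to 0.62), and 69.3% of them were higher. The intervals in this paragraph resampled single genes as if independent. Neighbouring genes changed alike, so the intervals are too narrow, and they cover no spread between libraries. Library scaling is argued against because the interval lies above the highest autosome median, 0.28. A trend with GC content or transcript length is argued against as the whole cause, because with the trend on GC content, length and expression removed the median was 0.4891 (0.34 to 0.58), more than 50% of its size. A uniform rise of the whole X chromosome is argued against by the bin from 165 to 170 Mb, whose upper quartile was -0.3918 over 13 genes, and by the bin from 105 to 110 Mb (-0.29 over 20 genes). These were picked as the lowest of 20 bins with at least 10 genes, and only these 2 had an upper quartile below 0. The median was above 0 in 16 of the 20. Segments of differing dosage stay open. Each gene's difference correlated with that of the next gene along the chromosome (r = 0.4125 across genes, at most 0.153 in 1000 random orders). Of the autosomes, chromosome 13, which holds the segment of lowered histone genes, was higher (0.544). The next highest autosome was chromosome 14 (0.284). Whether the histone genes raise the value of chromosome 13 was not tested, and RNA does not show copy number. Local regulation stays open too, as do the cell line, medium and passage, which were not tested. The X-linked noncoding RNA Xist was among the fixed list symbols but was not listed in the table.

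The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many called genes (7714, highest other 0), as many at least 2-fold (2370, highest other 0) and as many list genes (403, highest other 0) in limma. In the other splits edgeR's quasi-likelihood test also called 0 genes, and up to 168 genes had an unadjusted p under 0.05 in limma. Every other split mixes both cell forms in each group, so the difference between the forms becomes spread within the groups. Few or no calls could be foreseen there, and these counts cannot decide whether chance gave the calls. For gene lists called by camera, 3 of the 10 splits gave as many as the real one (8, highest other 8), and the other splits called between 3 and 8 lists.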
